A study of Mus musculus with 15 samples.

How the data were processed

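Transcript levels in mouse olfactory epithelium were measured on 15 Affymetrix MG_U74Av2 arrays, 1 per RNA pool, each pool made from 3 male C57Bl/6 mice of 6 weeks with 5 µg of RNA from each mouse. Per the labels the arrays fall into 5 groups of 3: untreated mice, sham-operated mice at day 5 after surgery, and mice at days 1, 5 and 7 after bilateral removal of the olfactory bulbs (olfactory bulbectomy, OBX). No array was left out, and 45 mice were used in all.

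The deposited values are signal intensities on a linear scale, 1 per probe set and array, made by the authors with array software whose name and version are not given in the sources used here. The mean signal after trimming 2% at each end was 1500.6 to 1500.7 on every array, so the authors scaled all arrays to a common trimmed mean. Deposited with each signal were a detection call and a detection p-value. The deposited array station settings, a kind of file described as other than a measurement, gave the scan day, the fluidics run and the chip lot, and were used only to form technical batches. The deposited series table holds the same signal intensities, with a largest difference of 0.0 from the values per array.

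Of 12488 probe sets, 66 were array controls and were left out. The annotation in the sources used here gave 10833 of the others 1 gene, 396 several genes and 1193 none, for 8251 distinct genes. Only probe sets with 1 gene are named. No genome build applies and no positions are given. Depth has no meaning for arrays, and the number of arrays limits the precision.

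Signals were raised to a floor of 1 (1 value was affected) and log2 transformed. Probe sets called present on at least 3 of the 15 arrays were tested, 7508 in all. A linear model with 1 mean per group was fitted to all 15 arrays in limma 3.58.1 under R 4.3.3, with moderated variances and a variance trend (prior degrees of freedom 4.52, residual degrees of freedom 10). Every comparison and the F test among the 5 groups were adjusted by the Benjamini-Hochberg method within that comparison, with a threshold of 0.05. SE is the moderated standard error of the log2 change, and SD is the spread of the signal over the 3 arrays of a group. All probe set p-values are two-sided. A change written as a value with ± and no unit is a log2 change ± SE, and signals are written ± SD.

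The comparisons were sham with untreated, OBX day 5 with sham, OBX days 1 and 7 with untreated, OBX day 5 with OBX day 1 and OBX day 7 with OBX day 5. OBX days 1 and 7 had no sham group of their own, so untreated mice served there, and each comparison was also made with the other control. The differences between time points in the change from control were tested as contrasts of the same model.

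Gene lists were written, and the comparisons, thresholds, filters, naming rule and first set of alternatives were chosen, before the data were examined. There were 29 lists: mature olfactory sensory neuron, neuronal and synaptic, immature olfactory sensory neuron and axon growth, odorant receptor, globose basal cell and neuronal progenitor, horizontal basal cell, cell cycle, sustentacular cell and xenobiotic metabolism, Bowman gland and secretory, ciliated respiratory cell, ensheathing and Schwann glia, macrophage and monocyte, lysosome, neutrophil and granulocyte, chemokine and cytokine, antigen presentation, complement and acute phase, interferon response, lymphocyte, apoptosis, immediate early and stress, extracellular matrix and wound repair, growth factor and receptor, chromatin and gene silencing, erythrocyte, skeletal muscle, bone and cartilage, endothelial, and ribosomal protein. A list was tested when at least 5 of its genes were measured, each by its brightest tested probe set (5740 genes), which held for 27 lists; the skeletal muscle and ciliated respiratory cell lists had too few. The lists were compared with all other genes by camera with a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals and by fry. Camera p-values were adjusted over the 27 lists.

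The text names genes by rule. Of the markers chosen in advance, Omp, Gap43, Neurog1, Pcna and Cd68 are given wherever measured, and 1 is not reported here. In each comparison of OBX with a control the 8 largest rises and 8 largest falls could be named, and 5 each in the other comparisons. They had to pass the test, be present on all 3 arrays of the higher group, have groups that did not overlap, and move the same way against the other control. From each list with a changed member, up to 4 members with the smallest adjusted p could be named; where nothing passed, the 4 probe sets with the smallest p. A fold against a group in which no array called the probe set present is given as a lower bound. It sets the mean of the brighter group against the mean, per array, of the higher of its own signal and the lowest signal called present. The smaller of the ratios on the log2 and linear scales is given, and it does not cover the spread between arrays. Fitted log2 changes of such probe sets serve only to compare settings and time points, and are no bounds.

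Overlap between comparisons was tested by two-sided Fisher exact tests over the 5740 genes. Calling was tested on simulated data drawn from the untreated means, with 1 spread per probe set pooled over the 5 groups. Changes of known size were put into 50 probe sets per size. In OBX day 5 against sham, 42%, 62%, 94% and 100% of changes of 1.5, 2, 3 and 4-fold were found, with 8 false calls among 7508 probe sets. The other comparisons found 24% to 44% at 1.5-fold and 72% to 90% at 2-fold, with 7 to 9 false calls. The wider spread of OBX day 5 was not simulated. The simulated comparisons differed only in the random draw and in which groups were set apart. Their shares therefore do not measure how well each real comparison called changes.

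Alternatives chosen in advance were quantile normalization, median-centred arrays, a pseudocount of 32, no filter, presence on at least 8 arrays, no variance trend, array weights, only the groups compared, replicate number as a block, scan day as a block, the series table values, a requirement of at least 1.5-fold, the other control, both controls together, and leaving out each array. Lists were also run as means over probe sets. Added after seeing the data were fluidics run as a fixed and as a random block, fits within 1 scan day, and a fit without immunoglobulin and muscle probe sets. Random blocks used statmod 1.5.0. The estimated correlation within fluidics runs was −0.25, where an effect shared by the arrays of a run would give a positive value. Counts with this random block are therefore no correction for a run effect. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Image files and probe-level intensities were not used here.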

Results

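Transcript levels were measured in olfactory epithelium of untreated mice, of sham-operated mice at day 5, and of mice at days 1, 5 and 7 after bilateral olfactory bulbectomy (OBX), an operation that removes the target of the olfactory sensory neurons. Each of the 5 groups had 3 arrays, and each array carried RNA pooled from 3 mice. By its title the series concerns the death and replacement of these neurons. Between 49.1% and 58.8% of probe sets were called present per array, and the median signal lay between 620.7 and 715.5. Arrays of the same group correlated at 0.965 to 0.986 across probe sets in untreated, sham, OBX day 1 and OBX day 7 mice, and at 0.914 to 0.970 in OBX day 5 mice. The median SD within a group was 0.28 on the log2 scale at OBX day 5 and 0.13 to 0.15 in the other groups. On the first principal component, which held 33.8% of the variance, untreated and sham arrays lay between −18.8 and −14.1, OBX day 1 between −10.1 and −5.6, and OBX days 5 and 7 between 7.6 and 39.3. The highest of these was OBX day 5 replicate 1, which also stood apart on the second component at 41.2 (21.9% of the variance).

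The arrays were scanned on 2 days. Untreated, sham and the first and second OBX day 1 arrays were scanned on the first day, and the third OBX day 1 array and all OBX day 5 and day 7 arrays on the second. OBX day 5 against sham and OBX day 7 against untreated therefore lie across scan days, and 1 OBX day 1 array links them. Estimates with scan day as a block rest on that array and are given beside each comparison. The arrays also fell into 4 fluidics runs, and OBX day 7 had a run of its own.

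Sham surgery was compared with no treatment to measure the effect of the operation without removal of the bulbs. Omp, the olfactory marker protein of mature sensory neurons, had a signal of 38910 ± 449 (SD, n = 3) in sham and 39190 ± 1840 in untreated mice (log2 change −0.01 ± 0.29 SE, adjusted p = 1.0). Gap43, a growth cone protein of immature neurons, differed by −0.07 ± 0.09, Neurog1, a transcription factor of neuronal progenitors, by 0.13 ± 0.24, Pcna, a DNA replication clamp, by 0.11 ± 0.12, and Cd68, a macrophage lysosomal protein, by 0.04 ± 0.15 (log2 ± SE, adjusted p = 1.0 for each). None of the 7508 probe sets passed the limma test (0 changed, smallest adjusted p = 0.745), 112 had an unadjusted p under 0.05 where chance gives 375, and no other tool was run on single probe sets. The smallest p belonged to Slpi, a secreted protease inhibitor, at −1.36 ± 0.26 (adjusted p = 0.74), followed by Ube4b, a ubiquitin ligase, at −0.75 ± 0.16 and Ptgr1 at −0.77 ± 0.17 (adjusted p = 0.89 for both). Dio1, a deiodinase, was called absent on all sham arrays and was at least 1.49-fold lower there (adjusted p = 1.0; fitted log2 change −3.13, and −4.16 with adjusted p = 0.028 without untreated replicate 3). Array weights called 2 probe sets, and leaving out untreated replicate 3 called 1.

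Camera called 5 of the 27 gene lists between sham and untreated mice, none with a changed member. The antigen presentation and interferon response lists were higher (adjusted p = 0.017 for both, and adjusted p = 0.76 for both with an estimated correlation). The sustentacular cell list (adjusted p = 0.021, and adjusted p = 0.76 with an estimated correlation), the Bowman gland list (0.026, and adjusted p = 0.63 with an estimated correlation) and the lymphocyte list (0.03, and adjusted p = 0.76 with an estimated correlation) were lower. Fry called 0 lists, with a smallest adjusted p of 0.98. The mature olfactory sensory neuron list (adjusted p = 0.93) and the cell cycle list (0.12) were not called. Without untreated replicate 1 the count was 2, without untreated replicate 3 it was 0, and without sham replicate 1 it was 11. Median, mean and test differed in sign for 8 lists, and no called list was among them.

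OBX day 5 was compared with sham surgery of the same day to find what removal of the bulbs changed. Transcripts of mature olfactory sensory neurons fell. Omp fell 3.56-fold, from a signal of 38910 ± 449 (SD, n = 3) in sham to 12380 ± 6910 (log2 change −1.83 ± 0.29 SE, adjusted p = 0.00058). Adcy3, the adenylyl cyclase of odour transduction, fell 5.01-fold, from 7983 ± 474 to 1653 ± 564 (−2.32 ± 0.17, adjusted p = 3.3e-06). Of the 14 measured genes of the mature olfactory sensory neuron list 10 fell, none rose and 4 did not pass (11 fell when adjusted over the list alone), with a median log2 change of −0.67 (adjusted p = 9.8e-07, and adjusted p = 0.069 with an estimated correlation). They included Cnga2, a subunit of the olfactory transduction channel (−1.56 ± 0.24), S100a5, a calcium-binding protein of these neurons (−1.35 ± 0.12), and Ebf3, a transcription factor of the same family as olfactory Ebf1 (−0.76 ± 0.12). Among 10 measured odorant receptors 8 fell and 2 did not pass (9 fell when adjusted over the list alone; median −0.96, adjusted p = 1e-06, and adjusted p = 0.012 with an estimated correlation). Olfr1507 fell 4.65-fold (−2.22 ± 0.34), Olfr1264 by 1.51 ± 0.21 and Olfr1509 by 1.42 ± 0.17 on the log2 scale, and Olfr92, absent on all OBX day 5 arrays, was at least 3.19-fold lower.

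The neuronal and synaptic list was called downward: 15 of its 24 measured genes fell, 2 rose and 7 did not pass (15 and 3 when adjusted over the list alone; median −0.58, adjusted p = 1e-06, and adjusted p = 0.073 with an estimated correlation). Chga, a secretory granule protein, fell 4.54-fold from 11840 ± 535 to 2764 ± 1130 (SD, n = 3; −2.18 ± 0.21 SE, adjusted p = 1.3e-05) and was at least 2.31-fold lower on a dimmer probe set that was absent on all OBX day 5 arrays. The calcium sensor Syt1 changed by −2.07 ± 0.16, the vesicle fusion protein Snap25 by −1.82 ± 0.18 and the endocytic GTPase Dnm1 by −0.97 ± 0.12. Scg2, another secretory granule protein, rose by 0.82 ± 0.15 (adjusted p = 0.0014). The other large falls were those of Vsnl1, a neuronal calcium sensor (5.31-fold), Slc8a1, a sodium-calcium exchanger (5.18-fold), Clip4 (5.15-fold) and F8, coagulation factor VIII (4.5-fold; −2.17, and −1.56 and −2.86 without OBX day 5 replicates 1 and 2). Eomes, a T-box transcription factor of neuronal lineages, fell on both of its probe sets. On 1 it was absent on all OBX day 5 arrays and at least 5.1-fold lower (adjusted p = 0.0037; fitted log2 change −3.36, and −4.48 and −2.56 without OBX day 5 replicates 2 and 3). On the other, present on 1 of those arrays, it was 5.06-fold lower (−2.34 ± 0.26, adjusted p = 3.4e-05).

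Genes of cell division and of neuronal progenitors rose at day 5. Of 63 measured cell cycle genes 26 rose, none fell and 37 did not pass (29 rose when adjusted over the list alone; median 0.54, adjusted p = 5.8e-09, and adjusted p = 0.069 with an estimated correlation). Birc5, a protein of the mitotic chromosomal passenger complex, rose 2.2-fold, from 405.9 ± 46.4 to 894.7 ± 110 (SD, n = 3; 1.14 ± 0.15 SE, adjusted p = 0.00016). Kif2c, a mitotic kinesin, rose by 1.04 ± 0.16, Aurka, a mitotic kinase, by 0.95 ± 0.13, and Cks1b, a cyclin-dependent kinase subunit, by 0.87 ± 0.13. Tacc3, a spindle protein, was absent on all sham arrays and at least 3.88-fold higher. Pcna differed by 0.21 ± 0.12 and did not pass (adjusted p = 0.22).

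Among 20 measured genes of the globose basal cell and neuronal progenitor list 12 rose, 1 fell and 7 did not pass (15 and 2 when adjusted over the list alone; median 0.50, adjusted p = 0.00031, and adjusted p = 0.022 with an estimated correlation). Neurog1 rose 2.23-fold, from 504.8 ± 38.8 to 1160 ± 363 (SD, n = 3; 1.16 ± 0.24 SE, adjusted p = 0.0037). Hes6, a transcription factor of differentiating neurons, rose by 1.03 ± 0.16, the receptor kinase Kit by 0.77 ± 0.13 and Id2, an inhibitor of basic helix-loop-helix factors, by 0.53 ± 0.10, while Id4, another inhibitor of this family, fell by 0.83 ± 0.11. The immature olfactory sensory neuron and axon growth list moved both ways: 6 of 27 genes rose, 8 fell and 13 did not pass (7 and 8 when adjusted over the list alone). Its median was 0.01, its mean −0.10 and its test downward without passing (adjusted p = 0.56), the only sign difference among the lists of this comparison. Gap43 rose 1.3-fold (0.38 ± 0.09, adjusted p = 0.0078), Cxcr4, a chemokine receptor of migrating cells, by 1.00 ± 0.13 and the microtubule regulator Stmn1 by 0.53 ± 0.10, while the axon guidance receptors Plxna3 and Epha5 changed by −1.50 ± 0.11 and −1.51 ± 0.22.

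The macrophage, lysosome, antigen presentation, complement and interferon response lists were called upward. Of 27 macrophage and monocyte genes 11 rose, none fell and 16 did not pass (13 rose when adjusted over the list alone; median 0.62, adjusted p = 1.6e-06, and adjusted p = 0.14 with an estimated correlation). C1qb, a chain of complement C1q, rose 3.05-fold, from 1132 ± 195 to 3445 ± 455 (SD, n = 3; 1.61 ± 0.15 SE, adjusted p = 1.1e-05), Lyz2, the macrophage lysozyme, by 1.36 ± 0.17 and the lectin Lgals3 by 1.27 ± 0.13. Cd68 differed by 0.43 ± 0.15 (adjusted p = 0.063). In the lysosome list 14 of 31 genes rose, 2 fell and 15 did not pass (15 and 2 when adjusted over the list alone; median 0.20, adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation). The protease Ctsh was at 1.19 ± 0.12 and the acid phosphatase Acp2 at −0.88 ± 0.11. In the antigen presentation list 9 of 16 rose and 7 did not pass (11 rose and 1 fell when adjusted over the list alone; median 0.57, adjusted p = 0.00013, and adjusted p = 0.25 with an estimated correlation). B2m, the light chain of class I molecules, was at 1.22 ± 0.22 and the class I gene H2-D1 at 1.05 ± 0.14. In the complement and acute phase list 7 of 18 rose, 1 fell and 10 did not pass (8 and 1 when adjusted over the list alone; median 0.39, adjusted p = 0.0011, and adjusted p = 0.23 with an estimated correlation). The chaperone Clu was at 1.32 ± 0.16. In the interferon response list 10 of 27 rose, 2 fell and 15 did not pass (the same counts when adjusted over the list alone; median 0.50, adjusted p = 0.0085, and adjusted p = 0.36 with an estimated correlation). Ifitm3, a membrane antiviral protein, rose by 0.90 ± 0.12, and Ifit1, a classical interferon-induced gene, changed by −1.79 ± 0.30.

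Of the 8 largest rises of day 5, that of Tacc3 is given above. Lcn2, a siderophore-binding protein of granulocytes and epithelia, rose 6.43-fold (2.68 ± 0.60 SE, adjusted p = 0.0055, n = 3) on its brighter probe set, while a dimmer probe set gave −0.17 ± 0.19. Without sham replicate 2, whose signal was 7570 against 916.7 and 1028 on the other sham arrays, its change was 3.67, and against untreated mice it was 1.42 and did not pass (adjusted p = 0.11). Slpi rose 5.43-fold (2.44 ± 0.26) on its dimmer probe set, from a sham mean of 492.2 where untreated mice had 1303, and by 1.08 against untreated mice (adjusted p = 0.0085). Its brighter probe set rose by 0.52 ± 0.14 (adjusted p = 0.015). The chitinase-like Chil1 rose 5.33-fold and Ltf, lactoferrin, 3.28-fold, from 5981 ± 211 to 19800 ± 3630. Nme4, a mitochondrial nucleoside diphosphate kinase, was at least 3.5-fold higher. D17H6S56E-5 rose 3.18-fold. The collagen gene Col18a1 rose 3.27-fold on 1 probe set (1.71 ± 0.31), while its brightest (adjusted p = 0.28) and another (adjusted p = 0.16) did not pass. Both were absent on all sham arrays, with bounds of at least 1.2-fold and at least 1.37-fold. In the neutrophil and granulocyte list 4 of 16 genes rose (adjusted p = 0.077, not called), among them the chitinase-like Chil3 (2.36 ± 0.52; 3.04 without sham replicate 3 and 2.96 without OBX day 5 replicate 1) and the gelatinase Mmp9 (0.57 ± 0.15, and 0.38 ± 0.22 on a dimmer probe set that did not pass). In the chemokine and cytokine list 2 of 15 rose (1 when adjusted over the list alone; adjusted p = 0.39), Ccl9 by 1.27 ± 0.32 and Cxcl12, whose other probe sets were at 0.02 and 0.07, by 0.43 ± 0.14. No gene of the lymphocyte list passed among 9 (adjusted p = 0.61) and none of the erythrocyte list among 5 (adjusted p = 0.44). The lymphocyte list holds the immunoglobulin heavy chain gene Ighm by its brightest probe set, which was at 0.29 ± 0.32 (adjusted p = 0.55). Ighm has 7 tested probe sets. Another, the one displayed and the one whose signals differ most between arrays, passed (adjusted p = 0.034), with no present call on the sham arrays. Its signals were 16300, 461.6 and 6464 on the 3 OBX day 5 arrays.

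Support cell, matrix and other groups also shifted. In the sustentacular cell and xenobiotic metabolism list 13 of 28 genes rose, 1 fell and 14 did not pass (13 and 2 when adjusted over the list alone; median 0.34, adjusted p = 0.002, and adjusted p = 0.26 with an estimated correlation). Cyp1a1, a xenobiotic oxidase, rose by 1.28 ± 0.23 and Gsto1, a glutathione transferase, by 1.03 ± 0.15, while the sulphotransferase Sult1d1 fell 4.05-fold (−2.02 ± 0.34, and −1.42 without OBX day 5 replicate 1). In the extracellular matrix and wound repair list 16 of 41 rose, none fell and 25 did not pass (18 rose when adjusted over the list alone; median 0.38, adjusted p = 1.4e-06, and adjusted p = 0.073 with an estimated correlation). The basement membrane collagen Col4a1 was at 1.00 ± 0.14 and S100a6 at 0.91 ± 0.12. In the ribosomal protein list 10 of 23 rose and 13 did not pass (10 when adjusted over the list alone; median 0.23, adjusted p = 0.0013, and adjusted p = 0.26 with an estimated correlation). Rpl13a was at 1.30 ± 0.15. The bone and cartilage list (4 of 15 rose, 5 when adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.19 with an estimated correlation) and the endothelial list (2 of 14 rose; adjusted p = 0.034, and adjusted p = 0.31 with an estimated correlation) were called upward, with the tight junction gene Cldn5 at 0.97 ± 0.14. The horizontal basal cell list was called upward with no changed member among 11 (adjusted p = 0.034, and adjusted p = 0.36 with an estimated correlation). Its keratins Krt6a and Krt17 had signals of 13577 and 2377 on OBX day 5 replicate 3 and at most 1110 and 812.5 on the other 14 arrays, and the same array had the highest signal for 18 of 38 skeletal muscle probe sets, where 1 in 15 is 2.5.

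The remaining lists were not called. In the apoptosis list 4 of 37 genes rose and 7 fell (4 and 8 when adjusted over the list alone; adjusted p = 0.17). The apoptosis activator Bid was at 1.04 ± 0.17 and Cidea at −0.86 ± 0.13. In the immediate early and stress list 6 of 34 rose and 4 fell (adjusted p = 0.58). The transcription factor Myc was at 1.29 ± 0.29 and the quinone reductase Nqo1 at −1.50 ± 0.21. In the chromatin and gene silencing list 9 of 53 rose and 3 fell (adjusted p = 0.17). Uhrf1, a factor of maintenance DNA methylation, was at least 1.98-fold higher, and the corepressors Tle5 and Sin3b rose by 0.68 ± 0.14 and 0.61 ± 0.14. In the growth factor and receptor list 4 of 33 rose and 1 fell (adjusted p = 0.24). Igfbp2 was at 0.68 ± 0.12 and Bmp6 at −1.38 ± 0.25. The ensheathing and Schwann glia list (3 of 11 rose, 4 when adjusted over the list alone; adjusted p = 0.098) held the glial calcium-binding gene S100b at 0.78 ± 0.16, and the Bowman gland and secretory list (3 of 12 rose; adjusted p = 0.078) the trefoil peptide Tff2 at 1.39 ± 0.25.

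In total 1578 of 7508 probe sets changed between OBX day 5 and sham, 888 higher and 690 lower, and 953 of them by at least 1.5-fold. Against untreated mice the count was 1514. Camera called 16 of 27 lists, 13 upward and 3 downward, and 2 of them also with an estimated correlation. With scan day as a block 65 probe sets passed (17 higher, 48 lower) and 13 lists. The interferon response (adjusted p = 0.20), endothelial (0.27) and horizontal basal cell (0.20) lists lost their calls with the block. The median size of the 1578 changes was then 0.62 where it had been 0.64, while the median SE rose from 0.15 to 0.27. Adcy3 (−2.43, adjusted p = 0.0074), Syt1 (−1.97, 0.015), Plxna3 (−1.47, 0.014), Chga (−2.08, 0.036), Slpi (2.51, 0.039) and C1qb (1.40, 0.04) passed with the block, and Omp (−1.71, 0.19), Birc5 (1.08, 0.099), Neurog1 (0.88, 0.46) and Gap43 (0.36, 0.41) did not. With fluidics run as a fixed block limma called 0 (645 at an unadjusted p under 0.05, median size 0.61, median SE 0.31), and with only the 2 groups in the model it called 469. Array weights gave 2383 and fluidics run as a random block 3847. Both controls together gave 2261.

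**Figure D1:**
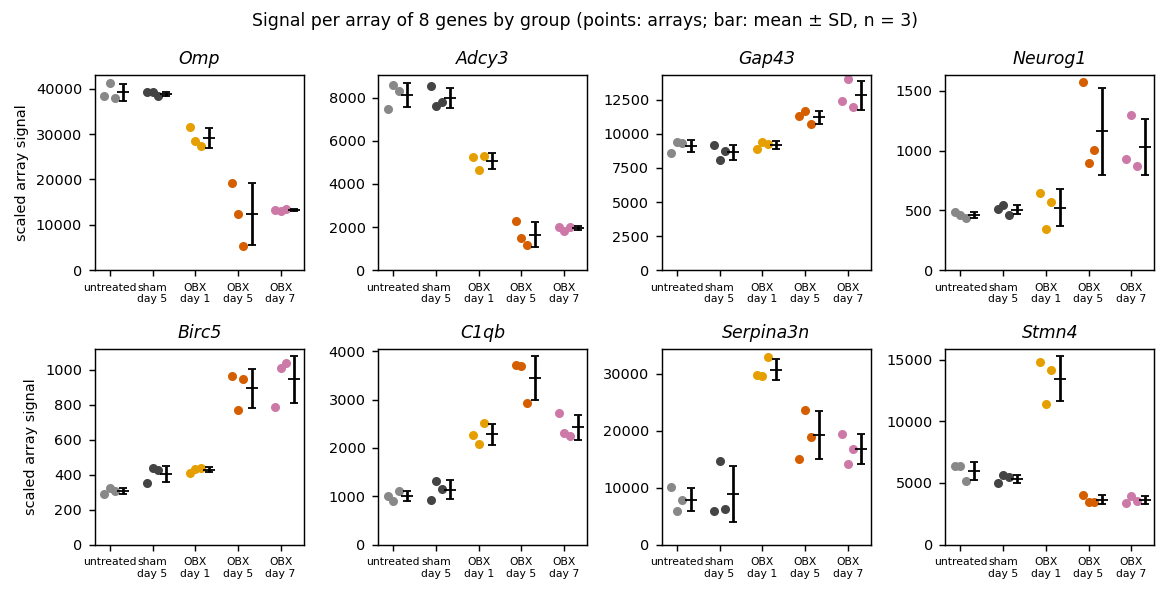
Signal per array (linear scale, arbitrary intensity units) of 8 genes in the 5 groups on the x axis, with points for arrays and bars for the mean ± SD (n = 3). Omp lay between 37996 and 41307 in untreated mice and between 5420 and 19232 at OBX day 5, while Stmn4 averaged 13450 at OBX day 1 against 5975 in untreated mice and 3652 at OBX day 5.

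OBX day 1 was compared with untreated mice to find the earliest changes. The 8 largest rises come first. Serpina3n, an acute phase protease inhibitor, rose 3.98-fold, from a signal of 7916 ± 2090 to 30780 ± 1900 (SD, n = 3; log2 change 1.99 ± 0.29 SE, adjusted p = 0.0021). Osmr, the receptor of oncostatin M, rose 3.66-fold (1.87 ± 0.29, adjusted p = 0.0031), and Cebpd, a transcription factor of the acute phase, rose 3.15-fold, from 1341 ± 161 to 4236 ± 551 (1.66 ± 0.15, adjusted p = 0.00018). Arg1, arginase of alternatively activated macrophages, was absent on all untreated arrays and at least 3.92-fold higher. Anxa1, a phospholipid-binding protein of leukocytes, rose by 1.73 ± 0.37 (another probe set, at 1.56 ± 0.49, did not pass), D17H6S56E-5 by 1.60 ± 0.28, the kininogen Kng1 by 1.55 ± 0.29 and Slpi by 1.48 ± 0.26, the last at 0.50 on another probe set that did not pass (adjusted p = 0.078). Against sham the change of Slpi was 2.84.

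The immediate early and stress list had 9 of 34 genes higher, none lower and 25 that did not pass (12 higher and 1 lower when adjusted over the list alone; median 0.28, adjusted p = 3.1e-08, and adjusted p = 0.11 with an estimated correlation). Ier3 rose by 1.11 ± 0.20, Xbp1, a factor of the unfolded protein response, by 0.85 ± 0.12 and Cebpb by 0.72 ± 0.11. Apoptosis genes were higher in 4 of 37 cases (5 higher and 2 lower when adjusted over the list alone; adjusted p = 0.35, not called), among them the death inducer Bcl2l11 at 1.00 ± 0.12 and the stress gene Gadd45a at 0.98 ± 0.14. In the complement and acute phase list 4 of 18 rose (9 higher and 1 lower when adjusted over the list alone; median 0.51, adjusted p = 1.8e-06, and adjusted p = 0.16 with an estimated correlation). Clu was at 1.22 ± 0.16. In the interferon response list 3 of 27 rose (8 when adjusted over the list alone; median 0.53, adjusted p = 1.8e-06, and adjusted p = 0.21 with an estimated correlation), Ifitm3 by 1.08 ± 0.12, the cytokine signalling inhibitor Socs3 by 1.02 ± 0.14 and Irf9 by 0.71 ± 0.12. Macrophage and monocyte genes rose in 2 of 27 cases (7 when adjusted over the list alone; median 0.28, adjusted p = 0.0005, and adjusted p = 0.25 with an estimated correlation), C1qb by 1.19 ± 0.15 and Lgals3 by 1.02 ± 0.13, while Cd68 was at 0.54 ± 0.15 (adjusted p = 0.094). In the lysosome list 5 of 31 rose (11 higher and 1 lower when adjusted over the list alone; median 0.13, adjusted p = 0.0003, and adjusted p = 0.21 with an estimated correlation). Ctsh was at 0.70 ± 0.12.

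In the extracellular matrix and wound repair list 8 of 41 genes rose (9 higher and 1 lower when adjusted over the list alone; median 0.07, adjusted p = 0.0059, and adjusted p = 0.25 with an estimated correlation), among them Ccn2, a matricellular growth factor, at 1.06 ± 0.17 and Timp1, an inhibitor of metalloproteases, at 1.00 ± 0.18. The endothelial list was called upward with 1 of 14 higher, Cldn5 at 0.81 ± 0.14 (adjusted p = 0.00012, and adjusted p = 0.21 with an estimated correlation). The ribosomal protein list was called upward without a changed member (adjusted p = 0.026, and adjusted p = 0.55 with an estimated correlation), and the lymphocyte list downward without one (median −0.47, adjusted p = 0.007, and adjusted p = 0.21 with an estimated correlation). Sustentacular cell genes rose in 4 of 28 cases (adjusted p = 0.088, not called).

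The mature olfactory sensory neuron, neuronal and synaptic, and odorant receptor lists were called downward at day 1. Omp, at 29120 ± 2200 (SD, n = 3) against 39190 ± 1840 in untreated mice without overlap, did not pass with an SE pooled over 5 groups (−0.43 ± 0.29, adjusted p = 0.55). In the mature neuron list Ebf3 fell by 0.76 ± 0.12 and 13 did not pass (4 fell when adjusted over the list alone; median −0.40, adjusted p = 0.00055, and adjusted p = 0.21 with an estimated correlation). Adcy3 was at −0.68 ± 0.17 (adjusted p = 0.054). Of 24 neuronal and synaptic genes Cplx2, a regulator of vesicle fusion, fell by 0.70 ± 0.13 (4 fell when adjusted over the list alone; median −0.23, adjusted p = 0.00055, and adjusted p = 0.21 with an estimated correlation). Among odorant receptors Olfr1264 fell by 0.84 ± 0.21 and Olfr71 by 0.62 ± 0.15, and 8 did not pass (7 fell when adjusted over the list alone; median −0.60, adjusted p = 1.1e-05, and adjusted p = 0.023 with an estimated correlation). Stmn4, a microtubule regulator of neurons, rose 2.25-fold, from 5975 ± 705 to 13450 ± 1820 (1.17 ± 0.13, adjusted p = 0.00024). The largest falls were those of Gfra2, a receptor of neurturin (−1.05 ± 0.21), Plxna3 (−1.01 ± 0.11), the cation transporter Slc22a2 (−0.98 ± 0.22), Pcp4l1 (−0.96 ± 0.19), Slc8a1 (−0.93 ± 0.19), Sfrp2, a secreted Wnt antagonist (−0.89 ± 0.10), and H2bc21, a histone (−0.87 ± 0.14).

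No cell cycle gene passed at day 1 among 63 (median −0.01, adjusted p = 0.80). Pcna was at 0.12 ± 0.12. Nor did a progenitor gene pass among 20 (adjusted p = 0.46). Neurog1 was at 0.13 ± 0.24 (log2 ± SE, adjusted p = 0.86) and Gap43 at 0.01 ± 0.09 (adjusted p = 0.98). In the growth factor and receptor list Igfbp4 rose by 0.78 ± 0.13 (another probe set, at 0.42 ± 0.23, did not pass) and the insulin-like growth factor binding protein Igfbp2 fell by 0.74 ± 0.12. In total 185 of 7508 probe sets changed, 135 higher and 50 lower, and 12 of 27 lists, of which the odorant receptor list alone held with an estimated correlation. Median, mean and test differed in sign for 5 lists, none of them called. Within the first scan day (3 untreated and 2 OBX day 1 arrays) 204 probe sets passed, 135 of them among the 185, with Omp at −0.39 (adjusted p = 0.019), Adcy3 at −0.72 (0.005), Serpina3n at 1.94 (0.016) and Cebpd at 1.64 (0.00087), and 12 lists were called. With scan day as a block 50 passed, and with fluidics run as a fixed block limma called 0 (296 at an unadjusted p under 0.05, median size 0.65 against 0.72, median SE 0.28 against 0.13). Against sham the count was 246, with array weights 992, with fluidics run as a random block 1492, with only the 2 groups in the model 454, and against both controls together 435. It was 105 without untreated replicate 1, 86 without untreated replicate 2, 86 without untreated replicate 3, 67 without OBX day 1 replicate 2 and 50 without OBX day 1 replicate 3.

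OBX day 7 was compared with untreated mice to measure the later state of the tissue. Omp was 2.95-fold lower, at 13290 ± 202 against 39190 ± 1840 (SD, n = 3; log2 change −1.56 ± 0.29 SE, adjusted p = 0.0029), and Adcy3 4.16-fold lower, at 1953 ± 110 against 8120 ± 566 (−2.05 ± 0.17, adjusted p = 1.2e-05). Of 14 mature olfactory sensory neuron genes 6 fell and 8 did not pass (8 fell when adjusted over the list alone; median −0.50, adjusted p = 2e-05, and adjusted p = 0.13 with an estimated correlation). Cnga2 was at −1.58 ± 0.24 and S100a5 at −0.96 ± 0.12. Of 10 odorant receptors 6 fell and 4 did not pass (7 fell when adjusted over the list alone; median −0.74, adjusted p = 6.6e-05, and adjusted p = 0.015 with an estimated correlation). Olfr92 was at least 3.69-fold lower and Olfr1264 at −0.87 ± 0.21. In the neuronal and synaptic list 13 of 24 fell, 3 rose and 8 did not pass (14 and 3 when adjusted over the list alone; median −0.52, adjusted p = 5.1e-05, and adjusted p = 0.18 with an estimated correlation). Chga fell 4.28-fold (−2.10 ± 0.21), with a dimmer probe set, absent on all OBX day 7 arrays, at least 2.31-fold lower, and Syt1 by 1.65 ± 0.16, while Scg2 rose by 1.02 ± 0.15. The largest falls also included Nqo1 (5.11-fold), Eomes on 1 of its probe sets (4.88-fold; the other, absent on all OBX day 7 arrays, was at least 4.02-fold lower and did not pass, adjusted p = 0.063), Clip4 (3.76-fold), the pacemaker channel Hcn2 (3.74-fold), Stom, an integral membrane protein (3.67-fold; a dimmer probe set, at −0.66 ± 0.41 with overlapping groups, did not pass, adjusted p = 0.32), and Olfm1, a secreted glycoprotein of neurons (3.51-fold).

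Cell cycle genes were higher in 31 of 63 cases, lower in none, and did not pass in 32 (45 rose when adjusted over the list alone; median 0.58, adjusted p = 3.4e-16, and adjusted p = 0.015 with an estimated correlation). Birc5 rose 3.06-fold, from 306.7 ± 19.1 to 945.1 ± 135 (SD, n = 3; 1.61 ± 0.15 SE, adjusted p = 2.4e-05), the mitotic kinesins Kif20a and Kif2c by 1.32 ± 0.17 and 1.17 ± 0.16, and Cks1b by 0.95 ± 0.13. Dtl, a ubiquitin ligase adaptor of DNA replication, was at least 5.19-fold higher, Dlgap5, a spindle protein, at least 2.85-fold, and Tacc3 at least 2.92-fold. As fitted log2 changes, Dtl was at 2.42, and at 1.77 against sham. Dlgap5 was at 1.78, at 0.79 against sham (adjusted p = 0.27, not passed) and at 2.38 without untreated replicate 3. Tacc3 was at 2.18, and at 1.39 without untreated replicate 1 (adjusted p = 0.085, not passed). Mybl1, a Myb family transcription factor, rose 3.47-fold, and Pcna was at 0.34 ± 0.12 (adjusted p = 0.071). Among progenitor genes 11 of 20 rose, 1 fell and 8 did not pass (14 and 2 when adjusted over the list alone; median 0.42, adjusted p = 6.9e-05, and adjusted p = 0.015 with an estimated correlation). Neurog1 rose 2.21-fold (1.14 ± 0.24, adjusted p = 0.0068), Hes6 by 1.00 ± 0.16, and the polycomb methyltransferase Ezh2 and the transcription factor Sox11 by 0.79 each (SE 0.14 and 0.11). Gap43 rose 1.41-fold, from 9100 ± 456 to 12820 ± 1090 (0.49 ± 0.09, adjusted p = 0.0024), and Cxcr4 by 1.06 ± 0.13, in an immature neuron list with 8 of 27 higher and 6 lower (adjusted p = 0.64). The chromatin list was not called (7 of 53 higher, 1 lower, adjusted p = 0.10).

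The antigen presentation, interferon response, macrophage and complement lists were called upward at day 7. The neutrophil and granulocyte list (median −0.10, adjusted p = 0.70) and the chemokine and cytokine list (median 0.18, adjusted p = 0.59) were not called. In the neutrophil list Chil3, a chitinase-like protein of macrophages and granulocytes, rose 11.3-fold, from 1589 ± 435 to 17580 ± 2310 (SD, n = 3; 3.50 ± 0.52 SE, adjusted p = 0.00056). Antigen presentation genes rose in 12 of 16 cases and fell in 1 (the same when adjusted over the list alone; median 0.84, adjusted p = 2e-05, and adjusted p = 0.25 with an estimated correlation), among them B2m at 1.31 ± 0.22, the class II gene H2-Aa at 1.23 ± 0.18 and Cd74, the class II invariant chain, at 1.07 ± 0.19. Interferon response genes rose in 13 of 27 cases (17 higher and 2 lower when adjusted over the list alone; median 0.70, adjusted p = 2e-05, and adjusted p = 0.25 with an estimated correlation). Ifitm3 was at 0.92 ± 0.12 and Irgm1 at 0.92 ± 0.21. In the same list the interferon-induced GTPase Ifi47 was at least 3.13-fold higher and Gbp2, a guanylate-binding protein, 3.08-fold higher. Macrophage and monocyte genes rose in 8 of 27 cases (8 when adjusted over the list alone; median 0.51, adjusted p = 0.00051, and adjusted p = 0.26 with an estimated correlation). C1qb was at 1.27 ± 0.15 and Cd68 at 0.06 ± 0.15 (adjusted p = 0.85). The complement list (5 of 18 rose; adjusted p = 0.043, and adjusted p = 0.47 with an estimated correlation), the extracellular matrix list (7 of 41; 0.0018, and adjusted p = 0.25 with an estimated correlation), the endothelial list (2 of 14; 0.042, and adjusted p = 0.44 with an estimated correlation) and the ribosomal protein list (5 of 23; 0.013, and adjusted p = 0.47 with an estimated correlation) were called upward. Serpina3n was at 1.11 ± 0.29 (adjusted p = 0.022), Col4a1 at 0.77 ± 0.14, Cldn5 at 0.80 ± 0.14 and Rpl13a at 1.08 ± 0.15. In the lymphocyte list (adjusted p = 0.64, not called) the B cell kinase Blk fell by 0.82 ± 0.22 and Jchain, the joining chain of polymeric immunoglobulin, was at 2.53 ± 0.81 (adjusted p = 0.054; 3.74 without OBX day 7 replicate 2, and 1.93 without replicate 1 or 3). Its signals were 5892, 475.5 and 5886 on the 3 OBX day 7 arrays, and the same displayed Ighm probe set had 18340, 450.8 and 13550 there (adjusted p = 0.064, with no present call on untreated arrays). The brightest Ighm probe set was at 0.30 ± 0.32 (adjusted p = 0.57).

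In total 978 of 7508 probe sets changed between OBX day 7 and untreated mice, 526 higher and 452 lower, and 602 by at least 1.5-fold. Against sham the count was 970. Of 27 lists 12 were called, 9 upward and 3 downward, and the cell cycle, progenitor and odorant receptor lists held with an estimated correlation. Median, mean and test differed in sign for 5 lists that were not called. With scan day as a block 13 probe sets passed, 1 higher and 12 lower, with the median size of the 978 changes at 0.60 against 0.66 and the median SE at 0.27 against 0.14. Nqo1 (−2.61, adjusted p = 0.0022), Stom (−1.74, 0.023), Adcy3 (−2.16, 0.026) and Plxna3 (−1.28, 0.029) passed with the block, Omp (−1.43, 0.45), Birc5 (1.56, 0.053) and Chil3 (3.25, 0.24) did not. With the block 10 lists were called, and the complement (adjusted p = 0.18) and endothelial (0.41) lists lost their calls. Array weights gave 2245, fluidics run as a random block 3083, only the 2 groups in the model 1711 and both controls together 1573. The count was 592 without untreated replicate 1, 621 without untreated replicate 3, 559 without OBX day 7 replicate 1, 592 without replicate 2 and 626 without replicate 3.

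**Figure D2:**
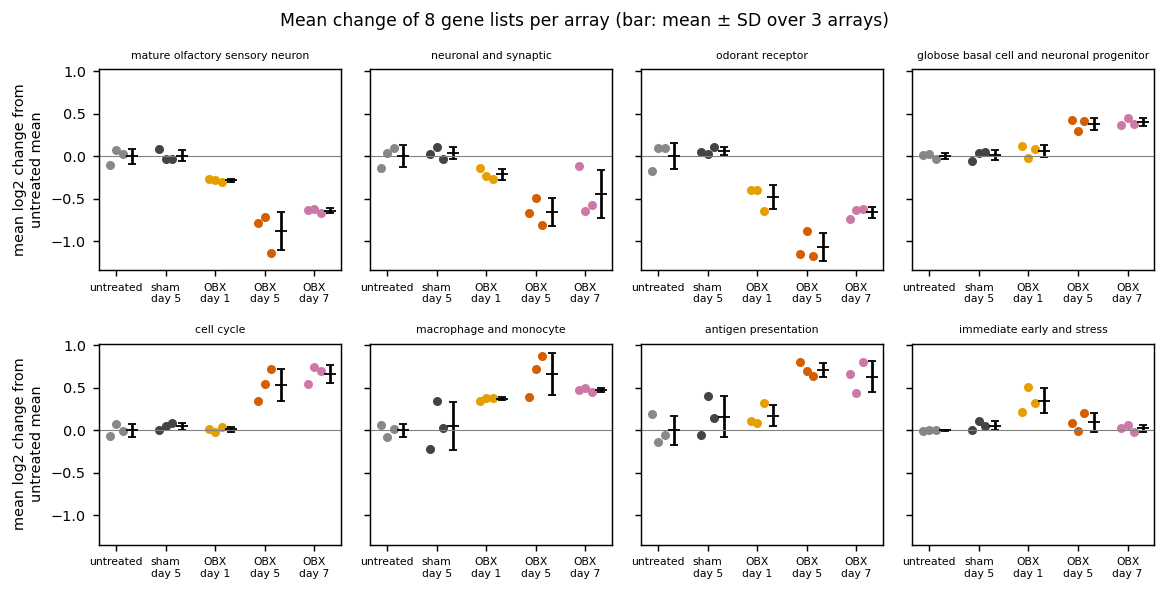
Mean log2 change from the untreated mean over the measured genes of 8 gene lists (y axis) for each array, by group on the x axis, with points for arrays and bars for the mean ± SD over 3 arrays. Cell cycle and progenitor genes lie near 0 at OBX day 1 and higher at days 5 and 7 (median changes 0.54 and 0.58 for cell cycle genes against controls), while immediate early and stress genes are highest at day 1 (median 0.28).

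OBX day 5 was compared with OBX day 1 to follow the change within operated mice. Stmn4 fell 3.67-fold, from 13450 ± 1820 to 3652 ± 345 (SD, n = 3; log2 change −1.88 ± 0.13 SE, adjusted p = 1.2e-06), and Igfbp2 rose 2.92-fold, from 1664 ± 133 to 4881 ± 739 (1.55 ± 0.12, adjusted p = 5.4e-06). Omp fell 2.66-fold (−1.41 ± 0.29, adjusted p = 0.0072). The largest rises were those of Chil3 (6.88-fold; 2.78, and 3.38 without OBX day 5 replicate 1), Cyp1a1 (4.63-fold), the cohesion factor Cdca5 (at least 3.09-fold), the interferon-induced Ifi27l2a (3.05-fold) and Rgr, a retinal-binding opsin (3-fold). The largest falls on the log2 scale were those of Eomes, F8 (5.81-fold), Clip4 (5.7-fold), Erlin1, an endoplasmic reticulum protein (at least 4.33-fold), and Sult1d1 (4.25-fold). Eomes was at least 3.68-fold lower on 1 probe set (fitted log2 change −2.90, −4.03 without OBX day 5 replicate 2, and −2.10 without replicate 3, where it did not pass) and 3.43-fold lower on the other. F8 was at −2.54 (−1.93 and −3.22 without OBX day 5 replicates 1 and 2) and Sult1d1 at −2.09 (−1.49 without replicate 1). Cell cycle genes rose in 24 of 63 cases and none fell (36 rose when adjusted over the list alone; median 0.50, adjusted p = 2.7e-17, and adjusted p = 0.014 with an estimated correlation). Aurka and the cyclin Ccnb2 were at 1.05 each (SE 0.13 and 0.14). Progenitor genes rose in 6 of 20 cases and 1 fell (12 and 1 when adjusted over the list alone; median 0.36, adjusted p = 0.00015, and adjusted p = 0.014 with an estimated correlation). Neurog1 was at 1.16 ± 0.24 and Hes6 at 1.08 ± 0.16.

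Mature neuron genes fell in 5 of 14 cases (7 when adjusted over the list alone; median −0.43, adjusted p = 0.00015, and adjusted p = 0.17 with an estimated correlation), neuronal and synaptic genes in 6 of 24 with 1 higher (11 and 1 when adjusted over the list alone; median −0.31, adjusted p = 0.00042, and adjusted p = 0.19 with an estimated correlation) and odorant receptors in 3 of 10 (6 when adjusted over the list alone; median −0.54, adjusted p = 0.00089, and adjusted p = 0.05 with an estimated correlation). Adcy3 was at −1.67 ± 0.17, Syt1 at −1.56 ± 0.16 and Olfr1507 at −1.35 ± 0.34. Immediate early and stress genes fell in 7 of 34 cases (12 lower and 1 higher when adjusted over the list alone; median −0.23, adjusted p = 0.00057, and adjusted p = 0.19 with an estimated correlation). Srxn1, an antioxidant reductase, was at −1.29 ± 0.17. Apoptosis genes fell in 4 of 37 cases (6 lower and 1 higher when adjusted over the list alone; median −0.12, adjusted p = 0.029, and adjusted p = 0.21 with an estimated correlation). They were Cidea (−1.15 ± 0.13), Ddit3, a stress-induced transcription factor (−0.93 ± 0.18), Bcl2l11 (−0.87 ± 0.12) and Bnip3 (−0.59 ± 0.13). Antigen presentation genes rose in 6 of 16 cases (7 when adjusted over the list alone; median 0.45, adjusted p = 5.1e-06, and adjusted p = 0.19 with an estimated correlation). H2-Aa was at 1.23 ± 0.18. Macrophage genes rose in 7 of 27 with 1 lower (10 and 1 when adjusted over the list alone; median 0.37, adjusted p = 0.00015, and adjusted p = 0.19 with an estimated correlation). The macrophage receptor Csf1r was at 0.71 ± 0.11 and Cd68 at −0.07 ± 0.15 (adjusted p = 0.81). Matrix genes (11 of 41 higher, 2 lower; adjusted p = 0.0004, and adjusted p = 0.19 with an estimated correlation), bone and cartilage genes (4 of 15; 0.00072, and adjusted p = 0.073 with an estimated correlation) and ribosomal protein genes (1 of 23; 0.016, and adjusted p = 0.43 with an estimated correlation) were called upward, with the fibrillar collagen Col5a2 at 0.67 ± 0.09. Gap43 was at 0.29 ± 0.09 (adjusted p = 0.057) and Pcna at 0.21 ± 0.12 (adjusted p = 0.30). Krt17 was called at 1.43 ± 0.41 (adjusted p = 0.048), with the signal of OBX day 5 replicate 3 given above, and was at 0.77 without that array (adjusted p = 0.079).

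In total 587 of 7508 probe sets changed between OBX days 1 and 5, 297 higher and 290 lower, and 12 of 27 lists, of which the cell cycle and progenitor lists held with an estimated correlation. Median, mean and test differed in sign for 7 lists that were not called. With scan day as a block 116 passed with a median size of 0.74, as without it. They included Stmn4 (−1.96, adjusted p = 0.00029), Igfbp2 (1.68, 0.00038), Adcy3 (−1.74, 0.0051) and Aurka (1.07, 0.014). Within the second scan day, where 1 OBX day 1 array stands alone and is assumed to vary like the other groups, 3 passed and Stmn4 was among them (adjusted p = 0.044), while 11 lists were called and the apoptosis list was not (adjusted p = 0.067). With fluidics run as a fixed block 23 passed, with that run as a random block 1550, with array weights 893 and with only the 2 groups in the model 80. The count was 344 without OBX day 1 replicate 1, 364 without replicate 2 and 339 without replicate 3.

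OBX day 7 was compared with OBX day 5 to follow the later course. Omp had a signal of 13290 ± 202 (SD, n = 3) at day 7 and 12380 ± 6910 at day 5 (log2 change 0.28 ± 0.29 SE, adjusted p = 0.70). Gap43 was at 0.19 ± 0.09 (adjusted p = 0.56), Neurog1 at −0.15 ± 0.24, Pcna at 0.01 ± 0.12 and Cd68 at −0.41 ± 0.15 (adjusted p = 0.56). No probe set passed the limma test (0 of 7508, smallest adjusted p = 0.0996), 601 had an unadjusted p under 0.05 where chance gives 375, and no other tool was run on single probe sets. The smallest p was that of the odorant receptor Olfr1509, at 1857 ± 66.5 against 910.2 ± 264 (1.07 ± 0.17), and the nuclear lamin Lmna was at −0.57 ± 0.12 (adjusted p = 0.41). The other probe sets of the 4 with the smallest p have no gene name. Without OBX day 5 replicate 2 the count was 14, and with fluidics run as a random block it was 979. The random block rests on a negative correlation within runs, so the 979 are no correction for a run effect.

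Camera called 12 of 27 lists between days 5 and 7, 4 upward and 8 downward, none with an estimated correlation, and fry called 3. The mature olfactory sensory neuron list (median 0.27, adjusted p = 0.0025, and adjusted p = 0.26 with an estimated correlation), the odorant receptor list (0.28, 0.0028, and adjusted p = 0.17 with an estimated correlation), the neuronal and synaptic list (0.19, 0.0037, and adjusted p = 0.33 with an estimated correlation) and the immature neuron list (0.13, 0.0043, and adjusted p = 0.26 with an estimated correlation) were higher at day 7. Adjusted over the list alone, 3 odorant receptors and 2 immature neuron genes rose. The macrophage list (median −0.18, adjusted p = 1.1e-05, and adjusted p = 0.24 with an estimated correlation), the extracellular matrix list (−0.17, 1.1e-05, and adjusted p = 0.17 with an estimated correlation), the lysosome list (−0.20, 8.5e-06, and adjusted p = 0.18 with an estimated correlation) and the complement list (−0.20, 0.0016, and adjusted p = 0.26 with an estimated correlation) were lower. So were the bone and cartilage list (−0.18, 0.0025, and adjusted p = 0.17 with an estimated correlation), the neutrophil list (−0.39, 0.0028, and adjusted p = 0.39 with an estimated correlation), the sustentacular cell list (−0.13, 0.007, and adjusted p = 0.42 with an estimated correlation) and the immediate early and stress list (−0.12, 0.04, and adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone, 7 macrophage, 3 complement, 2 matrix, 1 lysosome and 1 bone gene fell. Median, mean and test differed in sign for 3 lists, none called. All arrays of this comparison were scanned on 1 day but in different fluidics runs, so the run and the time point cannot be told apart.

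**Figure D3:**
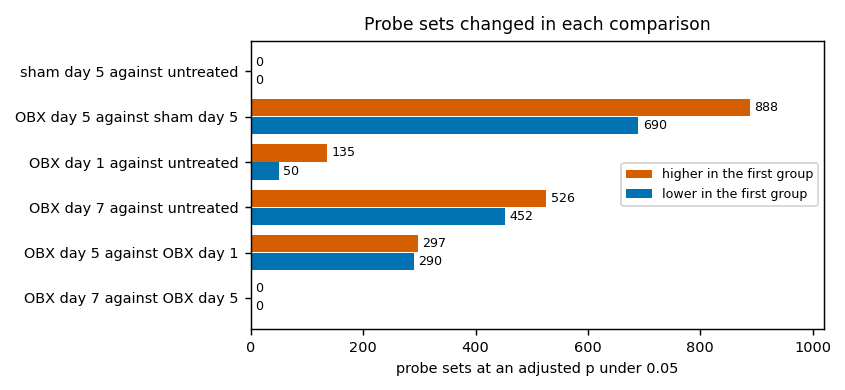
Number of probe sets (x axis) called higher and lower at an adjusted p under 0.05 in each of the 6 comparisons, of 7508 tested. OBX day 5 against sham had 888 higher and 690 lower, OBX day 1 against untreated 135 and 50, and sham against untreated and OBX day 7 against day 5 had 0.

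The calls of the time points overlapped more than independent lists would. Of 5740 genes, 718 were higher at OBX day 5 against sham and 429 at OBX day 7 against untreated, and 296 were in both, where independence gives 53.7 (two-sided Fisher exact p = 2.3e-186). Of genes called lower, 285 were in both, where independence gives 32.4 (p = 4e-262 by the two-sided Fisher exact test). None of the genes called at day 5 (0) was called in the opposite direction at day 7 in limma, and 98.5% of those higher and 98.1% of those lower had the same sign there. With OBX day 1 against untreated 85 higher genes were shared (13.9 by independence, two-sided Fisher exact p = 1.4e-55) and 30 lower genes (3.7, two-sided Fisher exact p = 1.2e-23), while 2 higher and 4 lower genes of day 5 were called the opposite way at day 1. The log2 changes of day 5 correlated across genes at 0.73 with those of day 7 and at 0.45 with those of day 1, and genes are not independent replicates. The 2 comparisons with untreated mice share their control arrays, while day 5 against sham does not share arrays with either. All comparisons use the same variance estimate per probe set, and those of days 5 and 7 both lie across scan days. Overlap above independence can therefore arise without a common effect of surgery. The Fisher p-values do not measure how far the time points agree. With scan day as a block 0 higher and 8 lower genes were shared with day 7, and 3 higher and 1 lower with day 1. Leaving out OBX day 5 replicate 1 raised the shared counts to 661 higher and 496 lower with day 7 and to 217 higher and 147 lower with day 1. Shared higher genes with day 7 numbered 192 without untreated replicate 3, 169 without OBX day 7 replicate 1 and 179 without its replicate 2. Shared higher genes with day 1 numbered 49, 40 and 37 without untreated replicates 1, 2 and 3, 26 without OBX day 1 replicate 2 and 21 without replicate 3. Shared lower genes with day 1 numbered 10, 8 and 11 without untreated replicates 1, 2 and 3, and 16, 10 and 5 without OBX day 1 replicates 1, 2 and 3.

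Among all 5 groups 1446 of 7508 probe sets differed by the F test (smallest adjusted p = 8.35e-07). Without OBX day 5 replicate 1 the count was 2351, with array weights 3181, with fluidics run as a random block 4937 and with scan day as a block 75.

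**Figure D4:**
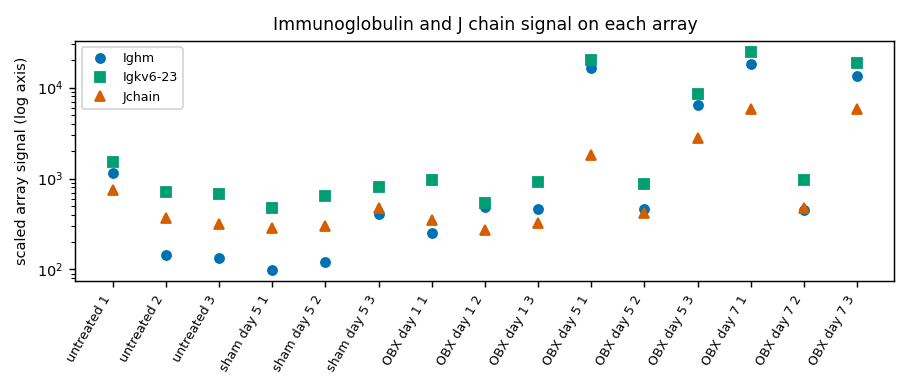
Signal per array on a log axis (arbitrary intensity units) of the immunoglobulin heavy chain gene Ighm (the displayed probe set of 7, not the brightest), the light chain gene Igkv6-23 and the joining chain Jchain for the 15 arrays on the x axis. Ighm stands at 16300 and 6464 on OBX day 5 replicates 1 and 3 and at 18340 and 13550 on OBX day 7 replicates 1 and 3, with at most 1161 on the other 11 arrays.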

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

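The tests of both scan day explanations, of lymphoid tissue and of the share of neuronal RNA were chosen only after the results they measure had been seen, while the test of antibody-secreting cells was chosen before.

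The change at OBX day 5 (against sham) was compared with the change at OBX day 1 (against untreated) in a test of the difference itself, which 111 of 7508 probe sets passed and 25 of the 165 named genes. The day 5 change minus the day 1 change (log2) was negative for Clip4 (−2.58, adjusted p = 0.00076), Osmr (−1.76), Stmn4 (−1.72), Vsnl1 (−1.69), Adcy3 (−1.64), Chga (−1.50), Snap25 (−1.49), Syt1 (−1.48), Slc8a1 (−1.44), Nqo1 (−1.38), S100a5 (−1.34), Cidea (−1.30), Bcl2l11 (−1.12), Cebpd (−1.08) and Dnm1 (−0.85). It was positive for Cyp1a1 (2.01), Igfbp2 (1.42), Gfra2 (1.35), Kif2c (1.08), Hes6 (1.0), Aurka (0.90), Kit (0.85), Lgals1 (0.82), Sfrp2 (0.80) and Ces1d (0.65). Stmn4 and Igfbp2 were called in opposite directions at days 1 and 5. These are single genes, and no gene list was tested for the difference. Other named genes that did not pass include Cnga2 (−1.02, adjusted p = 0.19), Cplx2 (−0.08, 0.89), Neurog1 (1.03, 0.18), Birc5 (0.66, 0.17), Pcna (0.09, 0.85), Serpina3n (−0.77, 0.45) and Cebpb (−0.55, 0.096). For Omp the difference was −1.40 ± 0.41 SE and did not pass (adjusted p = 0.12). The same test of day 7 against day 5 passed for 0 of 7508 probe sets in limma.

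These changes lie across scan days, and a difference between scan days is a candidate explanation for changes at days 5 and 7. With scan day as a block the median change of the probe sets called at day 5 was 0.96 of its value without the block, where a scan day effect would bring it toward 0. On the same probe sets the OBX day 1 array of the second scan day differed from the other OBX day 1 arrays by a median of 0.05 of the day 5 change. The block is estimated from this same difference, so both values are 1 measurement and not separate support. That measurement rests on 1 linking array, so the scan day and the time after surgery cannot be told apart here. The removal of the bulbs, which the design names, stays among the open explanations.

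Probe sets outside the tests, with too few present calls, were searched for a signal of at least 10 times the highest control array. On OBX day 5 replicate 3 the search found Krt13 at 5017.2 and 6118.3 on its 2 probe sets, Krt6a at 5176.3, Rptn at 3825.2, Krtap8-1 at 3527.2, Crct1 at 3318.6, Mt4 at 2972.4, Lgals7 at 2477.8, Krt25 at 2291, Sprr1b at 2174.6 and Krt2 at 1615.8. Genes of the skeletal muscle list were found on the same array: Acta1 at 5909, Myh4 at 1550.1, Myh1 at 1478.1, Atp2a1 at 1334.1 and Mb at 1304.1. Of 38 muscle probe sets 12 were called present there and on no other array. Cck reached 1424.9 on OBX day 7 replicate 1, Adck1 2252.7 on OBX day 7 replicate 3, and Amelx 2173.9 on OBX day 1 replicate 1.

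Immunoglobulin transcripts were far higher on replicates 1 and 3 of OBX days 5 and 7 than on the other arrays. The median change of 28 immunoglobulin probe sets at day 7 was 1.77 ± 0.33 (log2). Their median per OBX day 7 array was 2.82, −0.45 and 2.34 from the untreated mean. In this paragraph ± is an SE over probe sets or genes, which does not cover the spread between pools. Lymphoid tissue in the pools stays open: the median change of 6 B and T cell genes was −0.20 ± 0.32, but they went both ways. Blk was lower (−0.82, adjusted p = 0.023), Ltb, with no present call in untreated mice, at least 1.69-fold higher (adjusted p = 0.028), and Cd52 higher at day 5 (0.71, adjusted p = 0.03). Of 24 B and T cell probe sets 17, among them those of Cd79a, Cd79b and Cd3e, were never called present, and Cd37, also never present, reached 576.1 at days 5 and 7 against at most 182.1 in controls. Antibody-secreting cells in the pools may explain the signal, and 5 of their genes without Jchain had a median change of −0.03 ± 0.19, too wide to decide. The tissue makes some of these transcripts without surgery (Xbp1 had a mean signal of 6666 in untreated mice), so this stays open, as does a difference between mice.

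A lower share of neuronal RNA in the pool could raise the markers of every other cell type alike, without a change in those cells. The sustentacular list, at 0.24 ± 0.11 (mean log2 change at day 5 ± SE over genes), served as the reference. The macrophage list, at 0.61 ± 0.10, rose by 0.37 more than that, with an SE of 0.15 over genes and 0.30 over arrays. Per array this difference was 0.12, 0.52 and 0.87 at OBX day 5 and −0.23, 0.52 and 0.10 in sham, so the groups overlap and the test decides nothing. The Bowman gland, horizontal basal cell, neutrophil and lymphocyte lists were at 0.54 ± 0.14, 0.48 ± 0.13, 0.55 ± 0.23 and 0.55 ± 0.38. From the untreated mean, Bowman gland arrays were at −0.53, 0.02 and −1.10 in sham and 0.19, 0.12 and −0.30 at OBX day 5. Horizontal basal cell arrays were at 0.12, 0.12 and 1.21 at OBX day 5. The endothelial, bone and cartilage, ribosomal protein, glia and erythrocyte lists were lower, at 0.35 ± 0.08, 0.26 ± 0.09, 0.26 ± 0.07, 0.20 ± 0.12 and 0.25 ± 0.17. Cell cycle genes rose by 0.24 more than sustentacular genes (SE 0.13 over genes and 0.20 over arrays), which decides nothing either. Progenitor genes rose by 0.12 more (0.16 and 0.13), within both SEs, but went both ways (Neurog1 1.16, Id4 −0.83), which decides nothing. At OBX day 7 arrays were at −0.01, 0.13 and 0.08 from untreated for the sustentacular and 0.33, 0.5 and 0.27 for the endothelial list. They were 0.36, 0.45 and 0.38 for progenitor and 0.54, 0.75 and 0.70 for cell cycle genes. Only for cell cycle genes, above both lists, this argues against a lower share of neuronal RNA alone. These differences and changes in reference cells were not tested.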

How the results depend on the processing

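Fits by fluidics run, fits within 1 scan day, lists and overlaps with scan day as a block, overlaps without single arrays, and the fit without immunoglobulin and muscle probe sets were chosen after seeing the data, the other alternatives before. Scaling moved little: quantile normalization shifted the median of all probe sets by at most 0.026 and median-centring by at most 0.047 (log2). For OBX day 5 against sham the main count of 1578 was 1493 to 1607 with another normalization, pseudocount, filter or variance model, 1514 against untreated and 1580 without 32 immunoglobulin and muscle probe sets. Of all alternative values of named genes, 8593 stayed on the same side of the threshold, 1146 lost the call, 237 gained it and 0 reversed. For lists these were 1961, 156, 41 and 2. A change of sign was counted as reversed only where the main or the alternative value was called. Where neither was called, it was counted among the 8593 or the 1961. The number of arrays and the scan day limit what can be told; where no cause is named below, the cause was not tested.

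Array weights called 2 (sham against untreated), 2383 (OBX day 5 against sham), 992 (day 1), 2245 (day 7, both against untreated), 893 (day 5 against day 1) and 3181 (F test). With only the groups compared in the model, the counts were 469, 454, 1711 and 80 for OBX day 5 against sham, day 1, day 7 and day 5 against day 1. Of these, the comparisons with OBX day 5 fell (1578 and 587 in the main fit) and the others rose (185 and 978). The main fit pools the variance over all 5 groups, and OBX day 5 had the widest spread (median SD 0.28 against 0.13 to 0.15). Its part in these counts was not tested. Scan day as a block gave 65, 50, 13, 116 and 75 for the same comparisons and the F test; standard errors rose because 1 array links the days. Requiring at least 1.5-fold gave 953 for day 5 and 602 for day 7. Untreated and sham together gave 435 for day 1 and 1573 for day 7. Fluidics run as a random block, with a correlation of −0.25 within runs, gave 3847, 1492, 3083, 1550, 979 (day 7 against day 5) and 4937 (F test). An effect shared by the arrays of a run would give a positive correlation. These higher counts therefore do not correct for a run effect, and nothing is concluded from them. As a fixed block it gave 0 for day 5 (645 at an unadjusted p under 0.05), 0 for day 1 (296) and 23 for day 5 against day 1. Within 1 scan day 3 passed for day 5 against day 1, with 1 array on 1 side. OBX day 7 was a run of its own, so no fixed block could be fitted for it.

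Leaving out each array gave 0 to 1 (sham; 1 without untreated replicate 3), 1077 to 2054 (day 5), 50 to 130 (day 1), 559 to 677 (day 7), 339 to 835 (day 5 against day 1), 0 to 14 (day 7 against day 5; 14 without OBX day 5 replicate 2) and 1120 to 2351 (F test; 2351 without OBX day 5 replicate 1).

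With an estimated correlation 0, 2, 1, 3, 2 and 0 lists were called for sham, day 5, day 1, day 7, day 5 against day 1 and day 7 against day 5. Fry called 0 for sham and 3 for day 7 against day 5, and camera without the filter 0 for sham. Leaving out arrays gave 0 to 11 lists (sham; 2 without untreated replicate 1, 0 without untreated replicate 3, 11 without sham replicate 1), 13 to 18, 11 to 12, 10 to 12, 11 to 14 and 8 to 12. Without sham replicate 2 the complement list was called in the other direction (adjusted p = 0.039; 0.039 to 0.85 without single arrays) and the interferon list turned without a call (adjusted p = 0.98; 2.5e-07 to 0.98, lowest without sham replicate 1), both for sham against untreated.

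Genes shared between day 5 and day 1 numbered 3 higher and 1 lower with scan day as a block, and between day 5 and day 7 0 higher and 8 lower. Without single arrays they ranged from 21 to 217 higher and 5 to 147 lower with day 1, and from 169 to 661 higher and 204 to 496 lower with day 7, the highest each time without OBX day 5 replicate 1.

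Residuals of arrays with the same replicate number correlated at −0.35 to 0.37 (median 0.05, 30 pairs), of other numbers at −0.35 to 0.30 (median −0.02, 60 pairs). The ranges overlap, so pairing by replicate number was neither shown nor excluded. With replicate number as a block the counts were 0, 1534, 156, 924, 573, 0 and 1340 (F test), and the lists 5, 16, 12, 11, 12 and 11.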

Other observations

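The split tests in this part were chosen before their results were seen.

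Secretory proteins of the nasal glands varied widely between pools. At OBX day 7 the lipocalin Lcn3 had a mean signal of 6953 against 7549 in untreated mice, the odorant-binding protein Obp1a 13970 against 32990 (log2 change −1.33 ± 0.70 SE, adjusted p = 0.23), and Mup5, a major urinary protein, 5431 against 16380 (−1.43 ± 0.83, adjusted p = 0.27), none of which passed. In the same list Tff2 and Reg3g, an antimicrobial lectin, rose (1.07 ± 0.25 and 0.50 ± 0.12, adjusted p = 0.012 for both). The median of the 12 genes was −0.20 while the camera test pointed upward without a call (adjusted p = 0.90). In the growth factor and receptor list Bmp6 was lower at day 7 (−1.28 ± 0.25, adjusted p = 0.0036), as at day 5.

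The arrays of each comparison were also split in every other way into 3 and 3. The 10 splits are too few for a share under 0.05, and the count of splits with a result as large includes the real one. For probe sets the real and highest other counts were 1578 and 4 for OBX day 5 against sham (1 split as large), 185 and 0 for day 1 (1), 978 and 0 for day 7 (1), 587 and 0 for day 5 against day 1 (1), 0 and 3 for day 7 against day 5 (10) and 0 and 0 for sham against untreated (10). The limma counts of 0 stand beside 601 and 112 probe sets at an unadjusted p under 0.05. For lists the real and highest other counts were 16 and 18 for day 5 (2 splits as large), 12 and 12 for day 1 (2), 12 and 13 for day 7 (3), 12 and 9 for day 5 against day 1 (1), 12 and 8 for day 7 against day 5 (1) and 5 and 8 for sham (5). Every other split sets 2 arrays of 1 group and 1 of the other against the reverse, so it keeps part of the real difference. A split of this kind called 18 lists, more than the real 16. It therefore cannot tell how often camera with the preset correlation calls lists without a difference. For the F test 1 of 100 drawn splits, the real one, gave as many as 1446 probe sets, the highest other giving 16, so chance is excluded there at 0.05.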
